A study of Saccharomyces cerevisiae with 35 samples.

How the data were processed

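Yeast was grown overnight in rich medium with glucose, and genomic DNA was extracted on commercial columns and given its dye by random priming, per the labels. The test genome carried Cy3 and S288c carried Cy5 on all 35 arrays, with no dye swap. The scanner files hold intensity values that, per the file headers, were extracted by Agilent Feature Extraction 9.5.1.1 (20-, 25- and 30-mer arrays) or 9.5.3.1 (isothermal arrays). Per the file headers, the processed intensity of each channel was background-subtracted, spatially detrended and dye-normalised by a linear method on a list of probes. In every set the listed probes lay beside the site in their name, and outside the 20-mers some held another listed site. Mean and background intensity of each spot were deposited beside it. The deposited series tables hold log2 values that equal the log2 ratio of processed Cy3 to processed Cy5 wherever a value is present, with some values left empty for reasons not given in the sources used here.

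Probe names gave the chromosome, the listed site, and the probe's start and end. A probe was called covering when the site in its name lay inside it and flanking when it lay beside it and held no listed site. The headers of the fixed-length files name the sacCer1 build. Those of the isothermal files name a build that is not of yeast, and their probe names share the listed sites of the other sets, so sacCer1 coordinates are given throughout. No annotation of that build was used, so tests per gene, gene lists, and coding against intergenic sequence, planned before the data were examined, were not run. CAN1, GAP1 and FCY1 are named by the files, and their reading frames were read from the tiled probe sequences, in which 0 bases disagreed between sets. What the letter codes in the sample titles stand for is not given in the sources used here. On each isothermal array 6110 spots without a position in their name were not used.

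The log2 ratio of processed Cy3 to Cy5 was taken per probe, spots marked as outliers by Feature Extraction were left out, and each array was centred on the median of its flanking probes. The plan said only that arrays would be median-centred. The flanking probes were chosen once the probe names were seen and before any test, since most other probes cover a listed site. Probes were tested if Cy5 was well above background on at least 50% of the arrays in the fit. Site values are the median of the covering probes. A single fit of the 9 isothermal arrays at 60 °C (4 RM11-1a, 4 heterozygote, 1 self-hybridisation) was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, adjusted p under 0.05). The self-hybridisation is 1 array, whose spread was assumed equal to that of the others. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The fit was tested on simulated data with 200 of 233091 probes lowered by known amounts. For RM11-1a minus self, changes of -4 gave a median estimate of -4.06 and 50.0% were called, changes of -2 gave -1.96 and 0 were called, and changes of -1 gave -0.94 and 0 were called, with 1 false call. For RM11-1a minus heterozygote, 75.8% of the probes changed by -4 in RM11-1a were called, 1.49% of those changed by -2 and 0 of those changed by -1. For heterozygote minus self, 0 of the changed probes were called at any size. The real arrays hold far more changed probes, which relaxes the adjusted threshold.

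For detection, polymorphic regions were isothermal probes lower in RM11-1a with a log2 ratio of -1 or less. Unaffected regions were probes within 0.2 of 0 with no called probe within 100 nt. A probe of any set, isothermal included, belonged to a region if at least 50% of the shorter probe overlapped, whether or not it covered a listed site. On each array only probes with Cy5 well above background there were scored, by region and by probe name. Each RM11-1a and heterozygote isothermal array at 60 °C was scored on regions rebuilt without it. The self-hybridisation was scored on regions that it helped to define. Intervals come from a jackknife over chromosomes. Correlations used 100000 permutations, and sign permutations over chromosomes, like those over 4 against 4 arrays, were exact and two-sided. The rule for names, set before the data were examined, took the 15 most negative genes, the 5 most positive and up to 4 per list, none of which could be applied without annotation. It also took the 3 most negative called probes that are listed once, lie outside the named genes and have no other called probe within 200 nt, and these are given without the condition on named genes. Probe sequences listed once on the array stood in for sequences found once in the genome.

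Arrays were compared with each other before averaging. No pair of a probe set shared over 0.000849% of processed values in a channel, so all arrays were counted. Scan days fell into 14 batches. Isothermal arrays of both strains shared each scan batch, while fixed-length arrays of the strains were scanned on separate days. Alternatives covered the background correction (normexp, offset 50), loess within arrays (span 0.3, fitted on flanking probes), the deposited log2 table, the filter on dim probes, outlier spots, repeated sequences, the replicate number and the scan day as blocks, trend and robust moderation, a 2-fold threshold, a test against 0 and each replicate left out. Added after seeing the data were centring and loess on all probes, tests per site, detection by probe name, the fit within 1 scan day, and every comparison of site position, reference base, chromosome shifts, segments, runs and unresponsive sites, with their alternatives.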

Results

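Genomic DNA of budding yeast (Saccharomyces cerevisiae) was hybridised to 35 custom arrays of short probes, each array comparing a test genome in Cy3 with the reference strain S288c in Cy5. The test genome was RM11-1a, a haploid strain that differs from S288c at many positions, on 20 arrays. On 14 arrays it was the RM11-1a x S288c heterozygote, which carries both alleles at those positions. On 1 array it was S288c itself. The probes came in 4 sets that surround the same 24848 genome positions, called listed sites here because the probe names carry them. Probes of 20, 25 or 30 nt had a fixed length, and the isothermal probes ran from 16 to 35 nt so that their calculated melting temperatures lay close together (52.0 °C, SD 1.57 over probes, against 53.3 °C, SD 4.65, for the 25-mers). Arrays were hybridised at temperatures from 45 to 65 °C. The isothermal set at 60 °C had 4 arrays each of RM11-1a and the heterozygote, and every other combination had 1 array, so its values carry no replicate error. The share of probes with Cy5 signal well above background ran from 72.7% (RM11-1a, 20-mers, 60 °C) to 99.9% (RM11-1a, 30-mers, 55 °C). The number of arrays limits the precision of every value. The labels do not say that replicates came from separate cultures, so p-values from limma and from 4 against 4 arrays measure the spread between arrays only. Sign permutations over chromosomes, and the permutations of correlations, measure the spread over chromosomes and hold no spread between arrays. For site position each such p-value comes from 1 array.

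The first comparison asked how far a sequence difference lowers hybridisation when the Cy3 DNA comes from the differing genome only, with S288c DNA in Cy5 on the same array. RM11-1a DNA bound far less than S288c DNA to probes over listed sites, relative to the probes beside them, on whose median each array was centred. Over the 4 isothermal arrays at 60 °C, the median log2 ratio of the sites was -3.21, -2.73, -2.89 and -3.18 (SD 0.23, n = 4), against 0.0006 on the self-hybridisation. Of 24846 sites tested with limma, 23206 were lower in RM11-1a than in S288c at a Benjamini-Hochberg adjusted p under 0.05 and 17 were higher. Among single probes, 137266 of the 173456 probes covering a site were lower (79.1%), and 1067 of the 48972 flanking probes were lower (2.18%) while 915 were higher. All 233692 probes together gave 139565 lower and 1181 higher. The covering probes had a median difference of -2.89, while centring sets that of the flanking probes to about 0. Of the probes called lower, 2811 had no Cy3 signal well above background on any RM11-1a array, so that the size of the loss was not measured there. Log2 ratios given below for single probes, single sites, unresponsive sites, the heterozygote response and runs of probes are differences from the self-hybridisation.

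Of the 5 most negative sites, 3 lay close together on chromosome 8 (sacCer1 coordinates). These 5 were chosen after their values were seen. The 3 lay within a stretch of chromosome 8 (212950 to 216153) whose flanking probes were also low, with a median of -1.37, and site 1527411 on chromosome 4 lay just past such a stretch (1526814 to 1527408, median -3.36). Site 215632 on chromosome 8 had a log2 ratio of -6.93 (SE 0.72, limma adjusted p = 8e-07), and its neighbours at 215512 and 216124 had -6.28 and -6.05. Site 1527411 on chromosome 4 had -6.71 (SE 0.49) and site 196456 on chromosome 9 had -5.94 (SE 0.50, limma adjusted p = 6.1e-07 for both). The same 5 sites stood between -0.79 and -1.59 in the heterozygote. By the rule set before the data were examined, 3 single probes with no other called probe within 200 nt were named from 138 that qualified, and each covered 1 listed site. The probe on chromosome 2 at 441410 to 441433 had -5.26 (SE 0.93, limma adjusted p = 0.00044), with Cy3 well above background on 1 of the 4 RM11-1a arrays. Against a ratio of 0 in place of the self array this probe had -2.67, and the heterozygote minus the self array had -3.26 there (limma adjusted p = 0.36), so that the single self array made up much of its value. The probe on chromosome 14 at 252198 to 252218 had -4.82 (SE 0.91, limma adjusted p = 0.00065), with Cy3 well above background on 2 arrays. The probe on chromosome 12 at 370081 to 370106 had -4.28 (SE 0.55, limma adjusted p = 6e-05), with Cy3 well above background on all 4. With normexp background correction these 3 probes had log2 ratios of -0.48, -0.85 and -0.50 and none passed the test, nor did site 196456 at -0.99. The other 4 sites stood between -3.26 and -2.13 with normexp.

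A small part of the sites gave no drop in RM11-1a. At 709 sites (2.85%) the adjusted p was 0.05 or more and the log2 ratio was above -0.5. Their median was -0.04 in RM11-1a and -0.05 in the heterozygote, against -3.11 and -0.83 at the 23206 sites that fell. Chromosome 9 had the lowest share of such sites (1.91%) and chromosome 1 the highest (5.36%). On chromosome 16 between 23158 and 25656, 6 of 6 listed sites gave no drop. The flanking probes of that stretch were raised in RM11-1a (median 1.04), and 21 of the 709 sites lay in such raised stretches. Of all 709 sites, 133 stood next to another one along the chromosome. In 1000 random placements the highest number was 67. With normexp 9457 sites met the definition.

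These counts and sizes changed with the signals taken as input and with the centring. The normexp setting started from the mean and background signals in place of the processed intensities, and it added an offset. Background treatment was thus not the only step that differed from the main setting, and its part was not separated. With normexp on the mean and background signals, 46 probes and 37 sites were lower in RM11-1a. Centred on the median of all probes instead of the flanking ones, a choice added after seeing the data, 65501 probes were lower and 73376 higher, and 11170 sites were lower and 1240 higher. With loess fitted on all probes, also added, 23964 probes were lower and 23122 higher. The median site difference between RM11-1a and the self array was -3.01 in the main setting and -0.56 with normexp. It was -0.97 centred on all probes and -0.43 with loess on all probes.

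The second comparison asked what remains of the signal when each variant is diluted with a reference allele. The heterozygote was lower than S288c over the sites by a smaller amount than RM11-1a. The median of the sites was -0.81 ± 0.03 (SD, n = 4). As a difference from the self array it was -0.80, against -0.29 with normexp and -0.19 with either centring or loess on all probes. At 21006 sites (84.5%) all 4 heterozygote arrays lay below the self-hybridisation, where chance gives 20%. Single probes did not separate from the 1 self array after adjustment, since limma called 3 probes lower and 28 higher of 233823 and called 0 sites. At an unadjusted p under 0.05 there were 31647 probes lower and 704 higher, and 7000 sites lower and 6 higher. On simulated data the same test called 0 of 66 probes with a true log2 difference of -0.91. The 28 probes higher became 6, 14, 15 and 16 without heterozygote replicates 1, 2, 3 and 4, 44 with the deposited log2 table and 1 with outlier spots kept. Tested against a ratio of 0 without the self array, 116131 probes were lower and 4346 higher, and 20805 sites were lower. With no dye swap, that ratio keeps any dye effect of single probes. Centred on all probes, 4 were lower and 9 higher.

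RM11-1a and the heterozygote differed from each other at most sites. limma called 138876 probes and 22711 sites lower in RM11-1a, with 2900 probes and 53 sites higher. The probes higher became 1653 without RM11-1a replicate 3 and 1453 without replicate 4, and 1540 without heterozygote replicate 2 and 1624 without replicate 4. The sites higher became 34, 35, 26 and 32 in these 4 settings. The median site had a log2 difference of -2.14. This was -0.30 with normexp, -0.72 centred on all probes and -0.25 with loess on all probes. All 4 RM11-1a arrays lay below all 4 heterozygote arrays at 21245 sites (85.5%), where chance gives 1.43%. Arrays of both strains were scanned on each of 3 days, and the median site difference within a day was -2.36, -1.89 and -2.15, with 98.4%, 96.6% and 97.1% of sites lower. Centred on all probes, 74491 probes were lower and 81833 higher, and with normexp 62 were lower and 0 higher.

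The size of the heterozygote's drop was set against that of RM11-1a over 149848 probes chosen on RM11-1a replicates 1 and 2 and measured on replicates 3 and 4. The same self array was subtracted at both steps, so choice and measurement were not fully independent. The heterozygote's log2 ratio was 0.271 of that of RM11-1a (95% interval 0.264 to 0.279 from a jackknife over the 16 chromosomes). The 4 heterozygote arrays gave 0.273, 0.256, 0.270 and 0.282. The medians were -3.23 in RM11-1a and -0.87 in the heterozygote. An ideal mixture of both alleles in equal parts, computed per probe from the RM11-1a ratio, would have a median of -0.85. Compared probe by probe, the heterozygote minus this mixture had a median log2 difference of -0.07. On the linear scale the heterozygote lost 0.531 of what RM11-1a lost.

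Probe length and hybridisation temperature were varied to find where matched and mismatched targets separate. Within each strain and probe set, each temperature was scanned on days of its own. Isothermal and fixed-length arrays also differed in scan day and Feature Extraction version. Differences by temperature, or between isothermal and fixed-length sets, cannot be told apart from such effects. Among the RM11-1a arrays the isothermal probes at 60 °C, the 20-mers at 55 °C and the 25-mers at 65 °C detected the most, and the 30-mers the least at each temperature from 50 to 60 °C. A probe in a polymorphic region counted as detected when below the lowest 1% of the probes in unaffected regions of its own array. Except for the self-hybridisation, both kinds of region were taken from isothermal arrays other than the one scored. Polymorphic regions also took in probes that cover no listed site. On isothermal RM11-1a replicate 1 at 60 °C they held 216385 probes, while 172837 probes covered a site. The shares are therefore not rates for probes over a variant. Regions chosen by their response on isothermal arrays at 60 °C favour the isothermal set, so this scoring alone does not rank the sets. On the 4 isothermal RM11-1a arrays at 60 °C, 56.2%, 50.0%, 49.6% and 48.6% were detected, against 38.6% at 55 °C and 24.4% at 65 °C. The 25-mers gave 21.7% at 45 °C, 36.2% at 60 °C and 47.6% at 65 °C. The 30-mers gave 10.6% at 60 °C and 36.6% at 65 °C. The 20-mers rose from 10.9% at 45 °C to 50.3% at 55 °C and stood at 37.3% at 60 °C. Only probes with Cy5 well above background on the array were counted, so the probes scored differed between temperatures and sets. For the 20-mers they numbered 204980 at 45 °C, 188449 at 55 °C and 152301 at 60 °C. Jackknife intervals over chromosomes were wide, from 17.7% to 82.9% for the 20-mers at 55 °C and from 21.3% to 73.9% for the 25-mers at 65 °C. The heterozygote was detected far less: 11.9%, 2.05%, 10.2% and 2.22% on the 4 isothermal arrays at 60 °C, 4.64% with the 25-mers at 60 °C and 9.42% at 65 °C. The self-hybridisation gave 0.425%, but it helped to define its regions, so this is no independent rate of false detection. Scored by probe name, as described next, it gave 1.05%. The cut-off there is the lowest 1% of flanking probes on the same array, so about 1% follows without any sequence difference.

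Probes were also sorted by name, as covering or flanking a listed site. A covering probe counted as detected when below the lowest 1% of the flanking probes of its own array. Of the isothermal flanking probes at 60 °C, 2.18% were themselves lower in RM11-1a by limma. The cut-off can therefore fall among probes that lost signal, and strains and probe sets are compared at cut-offs that may differ for this reason. This scoring was added after seeing the data because the unaffected regions held few probes (3213 to 8435 per array), mostly in a tiled stretch of chromosome 6. Sorted by name, the 25-mers at 65 °C stood above the 20-mers at 55 °C. RM11-1a covering probes were detected in 74.8%, 69.4%, 61.2% and 70.1% on the 4 isothermal arrays at 60 °C, 72.4% with 25-mers at 65 °C, 42.3% with 25-mers at 60 °C, 52.8% with 20-mers at 55 °C and 41.8% with 30-mers at 65 °C. In the heterozygote the 4 isothermal arrays at 60 °C gave 26.3%, 11.5%, 15.8% and 12.7%, the isothermal array at 55 °C gave 20.0%, and the 25-mers gave 6.43% at 60 °C and 20.5% at 65 °C. The lead of isothermal probes over 25-mers at 60 °C was 14.9 points for RM11-1a in the region scoring (SD of the 4 arrays 3.47) and 26.6 points by name (SD 5.65). For the heterozygote it was 1.95 points in the region scoring, less than the SD of 5.19, and 10.1 points by name (SD 6.73). In the region scoring the RM11-1a lead turned to -15.1 points with normexp and to -1.30 points in regions that were also low on the 30-mer array, and the heterozygote lead to -3.67 and -2.37 points, and to -2.82 with loess. The temperature differences turned as well: with normexp, 25-mers at 65 minus 55 °C went from 9.49 to -1.75 points and isothermal probes at 60 minus 55 °C from 12.6 to -16.0. In regions also low on the 30-mer array the 25-mer difference was -8.40 points.

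**Figure D1:**
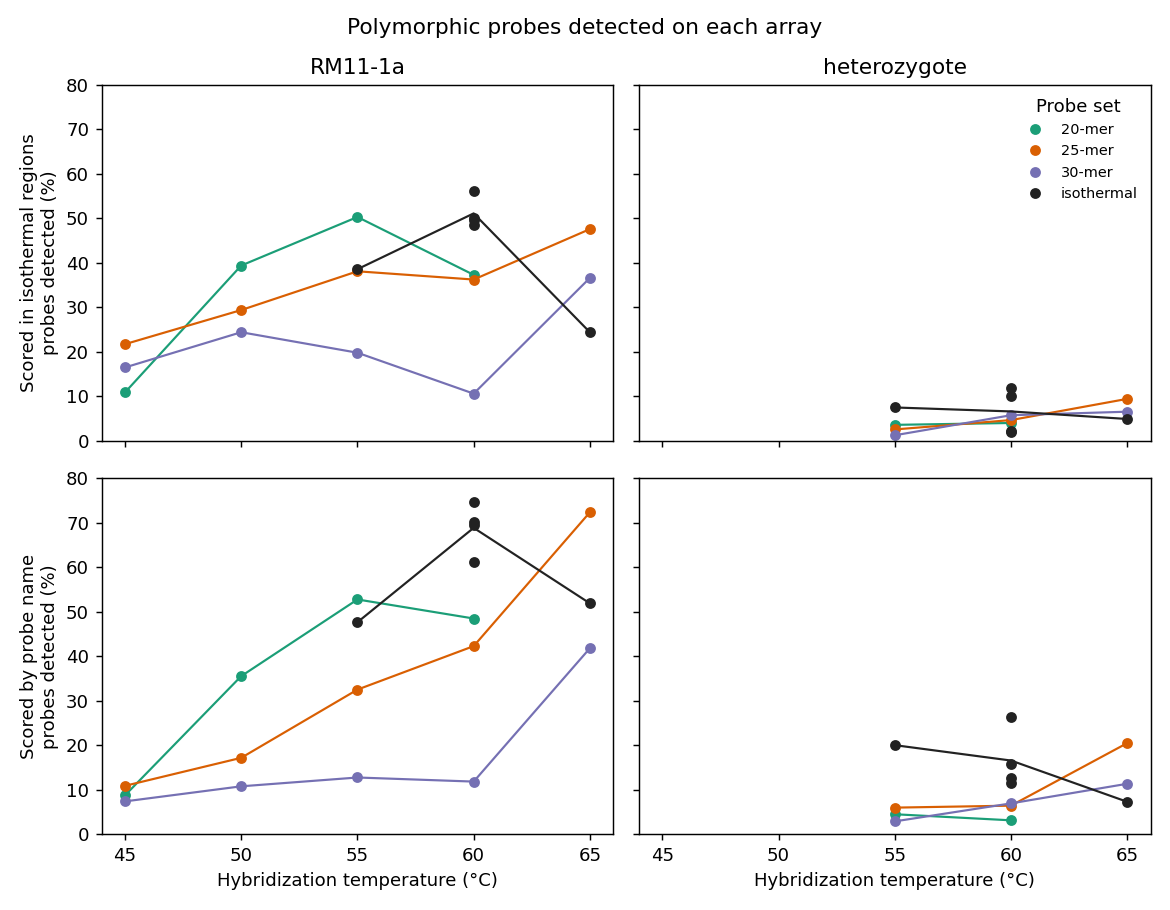
Share of probes detected (%, vertical axes) against hybridisation temperature (°C, horizontal axes) for RM11-1a (left) and the heterozygote (right). Scored are probes in polymorphic regions from isothermal arrays, covering a site or not (top), or probes covering a listed site by name (bottom). Only probes with Cy5 well above background on the array are counted. Each point is 1 array and lines join the means. Isothermal RM11-1a arrays peak at 60 °C (48.6% to 56.2%, top), while the 25-mers are highest at 65 °C (47.6%).

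The position of a site within its probe set the size of the drop. A site within 2 nt of a probe end lowered the ratio less than a site in the middle of 3 equal parts of the probe, on all 34 arrays of RM11-1a and the heterozygote and on 16 of 16 chromosomes in each. The exact sign permutation p over chromosomes was 3.1e-05 on each array, which is the smallest that 16 chromosomes allow and stays 3.1e-05 after adjustment over the 35 arrays. On isothermal RM11-1a arrays at 60 °C the medians at the ends ran from -1.08 to -0.91 and those in the middle from -3.64 to -3.10. With normexp the difference between ends and middle was 0.36, against 2.48. For 25-mers at 60 °C they were -0.41 and -1.37, and for the heterozygote on the same probes -0.22 and -0.59. The self-hybridisation showed no such difference (-0.003, sign permutation p = 0.09). Sites on the 3' side of the middle lowered the ratio less than sites on the 5' side on all RM11-1a arrays of fixed-length probes. On the 20-mers the gap was 0.04 to 0.09 (adjusted sign permutation p = 5.6e-05 to 0.028), and neither heterozygote 20-mer array passed (0.6 and 0.85). All heterozygote 25-mer and 30-mer arrays passed, with gaps of 0.02 to 0.15 (adjusted sign permutation p = 5.6e-05 to 0.002). It was 0.29 for RM11-1a 25-mers at 55 °C and 0.31 for 30-mers at 50 °C, on 16 of 16 chromosomes (adjusted sign permutation p = 5.6e-05 for both). After matching on reference base and GC content it was 0.22 and 0.30. The effect of matching varied between RM11-1a arrays. The gap fell from 0.086 to 0.049 for 20-mers at 50 °C and from 0.255 to 0.187 for 30-mers at 65 °C. It rose from 0.182 to 0.207 for 30-mers at 45 °C. On RM11-1a isothermal arrays the unmatched gap was 0.18 at 55 °C (16 of 16 chromosomes, adjusted sign permutation p = 5.6e-05) and 0.12 at 65 °C (15 of 16, adjusted sign permutation p = 0.00023). At 60 °C it was 0.03 to 0.07 for RM11-1a, where replicate 4 did not pass the test (adjusted sign permutation p = 0.063). For the heterozygote it was 0.05 at 55 °C and 0.04 at 65 °C (adjusted sign permutation p = 5.6e-05 for both). At 60 °C it was 0.0065, 0.0159, 0.0156 and 0.0082, and replicates 1, 3 and 4 did not pass (adjusted sign permutation p = 0.093, 0.2 and 0.32).

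**Figure D2:**
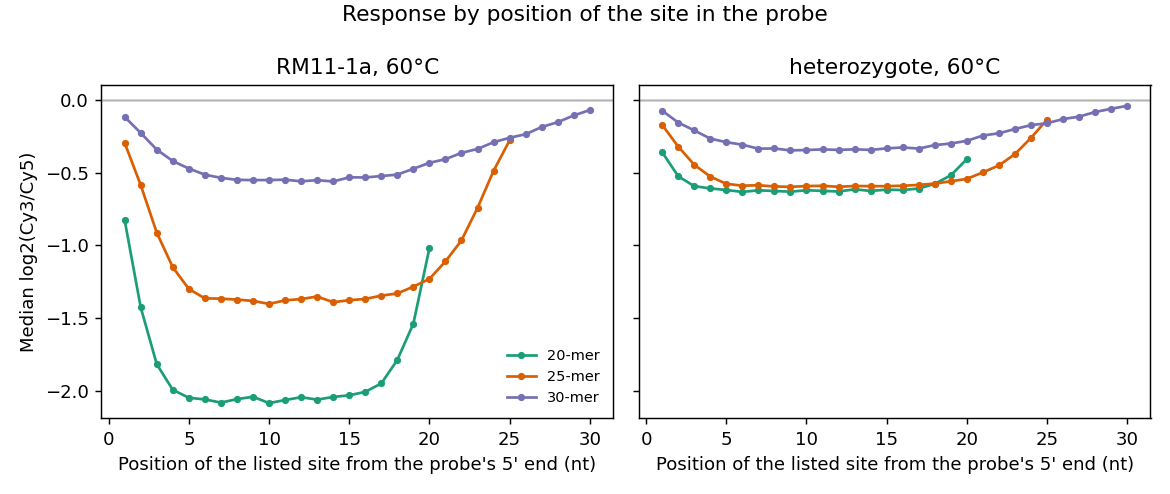
Median log2 ratio (vertical axes) by position of the listed site from the 5' end of the probe (nt, horizontal axes) at 60 °C for RM11-1a (left) and the heterozygote (right), 1 array per probe set. Sites near either end lower the ratio less than central sites, from -0.41 at the ends to -1.37 in the middle for RM11-1a 25-mers.

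The size of the drop also differed with the reference base at the site. Among isothermal probes with the site at least 5 nt from both ends, those with C on the probe fell furthest in RM11-1a, with a median of -4.25 ± 0.39 (SD, n = 4), then G at -3.55 ± 0.26, A at -3.34 ± 0.25 and T at -2.56 ± 0.17. The heterozygote medians were -0.97, -0.90, -0.84 and -0.80. C lay below T by a log2 difference of -1.69 on 16 of 16 chromosomes (sign permutation p = 3.1e-05). The 25-mers at 60 °C placed the bases in another order below C, at -1.60 for C, -1.38 for A, -1.20 for G and -1.15 for T. With normexp the difference between C and T was -0.17. Probes were not matched on length or GC content here, and their names do not give the variant base. The drop also varied with probe length. On isothermal RM11-1a replicate 1 at 60 °C the median was -3.80 for probes of 23 to 25 nt and -2.64 for those of 29 to 35 nt. The part of the base itself was therefore not separated.

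Tiled regions with a probe every 1 nt (fixed lengths) or 3 nt (isothermal) showed drops in fine detail at CAN1, GAP1, FCY1 and a stretch of chromosome 6. GAP1, the general amino acid permease, had 3 listed sites, and all 3 were covered by probes called lower by limma with a log2 ratio of -1 or less. They lay at 514740 (-3.27), 515253 (-1.63) and 516256 (-3.26) on chromosome 11. It also had 4 runs of 3 or more adjacent called probes over no listed site, all inside its reading frame of 602 codons (514705 to 516513, plus strand). These runs spanned 515298 to 515346 (median -3.19), 515334 to 515377 (-3.28), 515778 to 515805 (-2.89) and 516156 to 516198 (-4.04). In the heterozygote the same runs stood at -0.46, -0.80, -0.99 and -0.60. All of these are differences from the self array, whose own ratio was -0.81, -0.35, -0.05 and -0.56 in the runs. The RM11-1a 25-mer array at 60 °C, with no self array to subtract, had ratios of -1.32, -1.72, -0.84 and -1.65. CAN1, the arginine permease (chromosome 5, reading frame of 590 codons from 31694 to 33466, minus strand), had 3 listed sites, all found, and 0 runs elsewhere. FCY1, cytosine deaminase (chromosome 16, reading frame of 158 codons from 677162 to 677638), had 0 listed sites and 0 probes called. The chromosome 6 tile from 45450 to 74248 had 89 listed sites, of which 87 were found, and 42 runs over none.

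**Figure D3:**
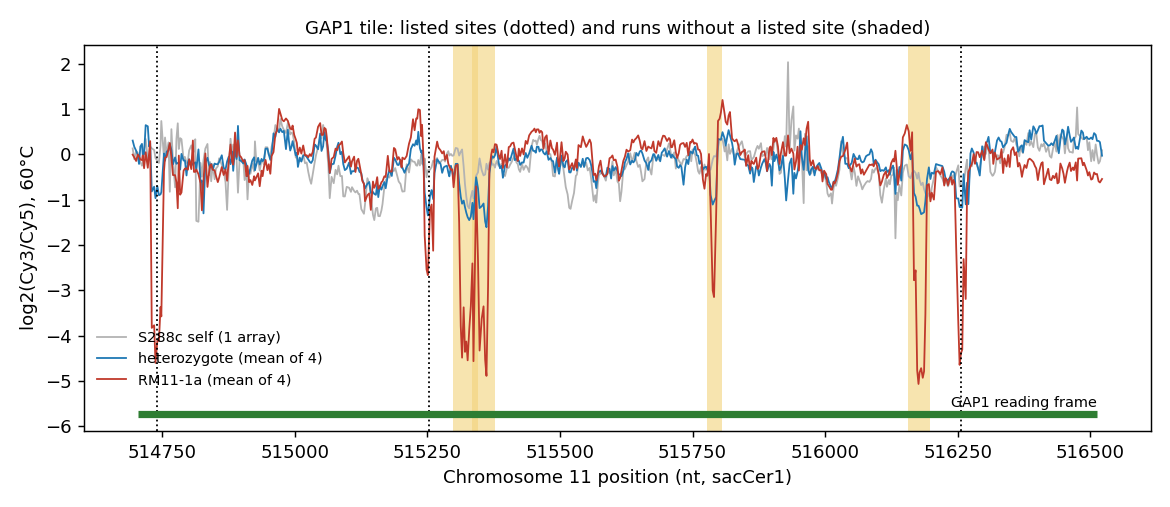
Log2 ratio (vertical axis) along the GAP1 tile of chromosome 11 (nt, sacCer1, horizontal axis) for RM11-1a and the heterozygote (means of 4 isothermal arrays at 60 °C) and the S288c self-hybridisation (1 array). Dotted lines mark the 3 listed sites, shading the 4 runs of called probes without a listed site, and the bar the reading frame; in the shaded runs the self-hybridisation has medians between -0.81 and -0.05, and RM11-1a minus the self-hybridisation between -4.04 and -2.89.

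The 46 runs without a listed site had a median log2 ratio of -3.31 in RM11-1a and -0.92 in the heterozygote. Some of the runs overlapped, such as 55842 to 55869 and 55854 to 55895 on chromosome 6, so 46 is not a count of separate places. On the 25-mer RM11-1a array at 60 °C, 45 of the 46 stood at -0.5 or less, and the heterozygote was below 0 in 45. The number of runs was 0 with normexp, 28 with centring on all probes and 8 with loess fitted on all probes. Outside called probes FCY1 had a mean of the array medians of 0.22 ± 0.31 (SD, n = 4) in RM11-1a and -0.23 ± 0.25 in the heterozygote (exact permutation p = 0.0571, adjusted 0.229). The exact permutation p was 0.857 for CAN1, 0.657 for GAP1 and 0.943 for chromosome 6. The smallest possible is 0.0286, which could not pass for a single tile after adjustment over the 4.

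Chromosome ends were compared with the rest because subtelomeric sequence varies between yeast strains. Within 20 kb of an end, taken from the last probed position on the right, 60.6% of 10863 probes were lower in RM11-1a, against 59.7% of 222829 elsewhere. The mean difference over the 16 chromosomes was -0.36 points (SD 11.2 over chromosomes, sign permutation p = 0.91). Counted by listed sites, a unit added after seeing the data, 88.9% of 1175 sites near the ends were lower and 93.6% of 23671 elsewhere. That mean difference was -7.17 points, with 12 of 16 chromosomes lower near the ends (sign permutation p = 0.0055).

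Probes that flank the sites also gave a value per chromosome, as a reading of how much of each chromosome was present. They were lower on the shortest chromosomes in both strains, and hardly so on the self-hybridisation, where chromosome 6 had -0.03. On isothermal arrays at 60 °C chromosome 1 had a median of -0.24 ± 0.03 (SD, n = 4) in RM11-1a and -0.18 ± 0.06 in the heterozygote, chromosome 6 had -0.18 ± 0.04 and -0.13 ± 0.01, and chromosome 3 had -0.14 ± 0.03 and -0.10 ± 0.05. Chromosome 9 had -0.03 ± 0.03 in RM11-1a and -0.10 ± 0.03 in the heterozygote. Over the 16 chromosomes the value rose with the last probed position, a relation computed for 3 groups of arrays and chosen after seeing the data. For RM11-1a Spearman's rho was 0.782 (permutation p = 0.00051, adjusted 0.00077) and Pearson's r was 0.893 (permutation p = 2e-05, adjusted 4e-05). For the heterozygote rho was 0.921 (permutation p = 1e-05, adjusted 3e-05) and r was 0.954 (the same p values, 1e-05 being the smallest that 100000 permutations give). Without chromosomes 1 and 6, the farthest from the median, r was 0.791 and 0.914. On the self-hybridisation rho was 0.338 (permutation p = 0.2, adjusted 0.2) and r was 0.417 (permutation p = 0.11, adjusted 0.13), falling to 0.0527 without these chromosomes.

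**Figure D4:**
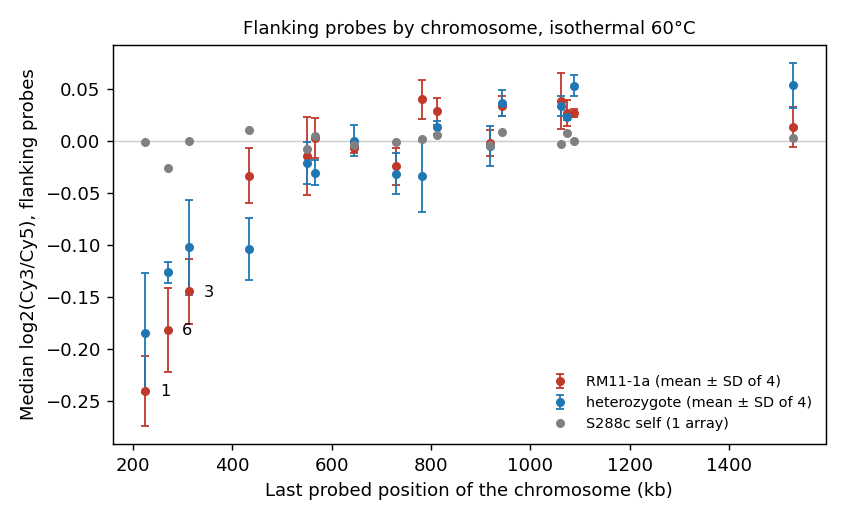
Median log2 ratio of flanking probes (vertical axis) against the last probed position of each of 16 chromosomes (kb, horizontal axis) on isothermal arrays at 60 °C, as mean and SD of 4 arrays for RM11-1a and the heterozygote and as 1 array for the self-hybridisation. Chromosomes 1, 3 and 6 are lowest in RM11-1a, at -0.24, -0.14 and -0.18.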

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

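The test of a fixed copy number, with its rule, was chosen after its values were seen, the requirement that an interval clear the bound was added after the values for unresponsive sites were seen, and the 3 patterns weighed were themselves found in these data.

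FCY1, the cytosine deaminase gene tiled on chromosome 16, had 1 heterozygote array far from the others. Isothermal replicate 2 at 60 °C had a median log2 ratio of -0.55 over the tile, while the other 3 stood between -0.12 and -0.07. It was 1 of 54 groups of arrays tested in this way, where chance gives 2.7. No explanation was tested.

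Chance as the source of the difference between RM11-1a and the heterozygote was examined by splitting the arrays in other ways. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many probes lower as the real split. That was the real split itself (138876 probes, against 0 at most in the others). Every other split mixes both strains within a group, which raises the spread there. The outcome was thus largely fixed in advance, and the splits do not exclude chance.

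Chromosomes 1, 3 and 6 had lower flanking probes than the other chromosomes on all 34 arrays of RM11-1a and the heterozygote, with a median log2 difference of -0.16 (range -0.50 to -0.04; median -0.106 with normexp) against -0.02 on the self-hybridisation. GC content as the whole cause was argued against, since the difference was -0.16 after adjustment for it, and so were unlisted variants under some probes, since the 75th percentiles differed by -0.15. Over 11 pairs of equal probe set and temperature the heterozygote minus RM11-1a difference had a median of -0.11 and was below 0 in 8, but its exact sign permutation p of 0.024 treats the pairs as independent, while the 8 fixed-length pairs (median -0.23, all below 0) share 3 pairs of scan days, which allow no p under 0.25. The 3 isothermal pairs scanned on the same days had a median of 0.05, all above 0 (exact sign permutation p = 0.25, the smallest that 3 pairs allow), so a fixed copy number difference cannot be told apart from effects of scan day or probe set. A difference in the DNA preparations or in growth between strains may also contribute and was not tested.

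Listed sites without a drop in RM11-1a numbered 709. Dim probes were argued against, since the median reference log2 signal at these sites differed from that at the others by -0.093. On the 25-mer RM11-1a array at 60 °C their median lay 75.5% of the way from the responding sites to the flanking probes (95% interval 69.1% to 81.9%), and on the 30-mer array 59.6% (52.9% to 66.2%). Insensitive isothermal probes and RM11-1a DNA carrying the reference base at these sites cannot be told apart, since the first interval spans the bound set for it and the second falls between the bounds. Both may hold for different sites, and 21 of the sites lay in stretches whose flanking probes were raised in RM11-1a. On the 25-mer array 325 of the 707 unresponsive sites with a value stood above -0.25, against 4.26% of the responding sites. The median GC content of the isothermal covering probes was 44.7% at unresponsive sites and 39.1% at responding sites.

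Called probes of the tiles that cover no listed site numbered 439, of which 375 (85.4%) lay in runs of 3 or more. Neighbouring probes start 3 nt apart, share most of their sequence and are set against the same self array. False calls could therefore fall in runs as well, so the runs do not decide on chance calls. An artefact of the isothermal arrays was argued against, as the 25-mers in these runs lay lower than elsewhere in the tiles by a log2 difference of -1.58. A candidate explanation is sequence variants absent from the list, as a hypothesis found and tested on the same data. Cross-hybridisation to related sequence was not tested.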

How the results depend on the processing

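Chosen after seeing the data were centring and loess on all probes, tests per site, scoring by name, chromosome ends by site, and all alternatives for site position, reference base, chromosomes 1, 3 and 6, segments, runs and unresponsive sites. Of 244 values of the 19 summary results under alternatives, 194 stayed the same by the rules for each kind of value, 38 moved, 8 reversed, 3 weakened and 1 became stronger. Of 159 values of named probes and sites 152 stayed past the threshold and 7 did not. Unless stated, the cause was not tested.

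With normexp, 46 probes (37 sites) were lower in RM11-1a than in S288c, 0 probes in the heterozygote, and 62 (314) in RM11-1a than in the heterozygote. Centred on all probes the first and last were 65501 (11170) and 74491 (12816), because the median probe covers a site, so that 43826 flanking probes turned higher. With loess on all probes they were 23964 (4281) and 38098 (6609), with 8 probes lower in the heterozygote than in S288c. Against a ratio of 0 the heterozygote had 116131 probes (20805 sites) lower and 4346 probes higher. There the single self array no longer limits the test, but with no dye swap a dye effect of single probes stays in the ratio. With Cy5 well above background on every array the heterozygote had 0 probes lower. Deviations of arrays with the same replicate number correlated by 0.22, 0.44, 0.16 and 0.03, so the numbers were not taken to pair the arrays. Replicates 1 and 2 correlated best with their own number in the other strain, each scanned on the same day, while 3 correlated best with 4 and 4 with 3, all scanned on 1 day. With replicate as a block 142914 probes were lower in RM11-1a than in the heterozygote, and with scan day as a block 144647.

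Without 1 replicate in turn, the probe counts were 137406 to 139984 (RM11-1a against S288c), 2 to 4 (heterozygote against S288c) and 131789 to 138485 (RM11-1a against the heterozygote), and the site counts 23035 to 23235, 0 to 0 and 22152 to 22641. The heterozygote response was 0.268 to 0.277, the end minus middle difference 2.41 to 2.55, the C minus T difference -1.78 to -1.58, runs 44 to 48 and unresponsive sites 663 to 773. Segments were 13 to 24, the highest without RM11-1a replicate 1.

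Detection differences are given in points. With normexp, 25-mers at 65 minus 55 °C gave -1.75, 30-mers 2.63, isothermal probes at 60 minus 55 °C -16.0, and isothermal minus 25-mer probes at 60 °C -15.1 for RM11-1a and -3.67 for the heterozygote. With loess, 30-mers gave 10.95, isothermal probes 18.3 and the heterozygote -2.82. In regions also low on the 30-mer array, 25-mers gave -8.40 and isothermal minus 25-mer probes -1.30 for RM11-1a and -2.37 for the heterozygote. With 80% overlap, 30-mers gave 21.9, isothermal probes 16.1 and the RM11-1a design difference 19.6, which was 11.2 at the 5th percentile. By name the 5 differences, in the order given for normexp, were 39.9, 29.1, 21.2, 26.6 and 10.1.

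The heterozygote response was 0.384 with normexp and 0.259 at log2 of -2 or less. With normexp the end minus middle difference was 0.36, the C minus T difference -0.17, the difference of chromosomes 1, 3 and 6 -0.11, segments 4, runs 0 and unresponsive sites 9457. Runs were 28 centred on all probes and 8 with loess on all probes. Segments were 33 at a threshold of 0.6. The share near chromosome ends was -7.17 points by site (sign permutation p = 0.0055). The 3 named probes had -0.48, -0.85 and -0.50 with normexp and -2.50, -1.29 and -1.08 with loess on all probes, and site 196456 on chromosome 9 had -0.99 with normexp. Signal over background limits the ratios, since Cy3 was well above background on 68.5% of the probes of the isothermal RM11-1a array at 65 °C.

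Planned tests per gene, of gene lists and of coding sequence were not run for want of an annotation of the build.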

Other observations

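All comparisons here were chosen after the data were seen. Stretches of the genome beyond single sites also differed from S288c. Ratios on isothermal arrays are differences from the self array. A running median of 7 flanking probes beyond 0.8 over at least 10 probes gave 14 segments in RM11-1a (8 lower, 6 higher), 6 in the heterozygote and 0 on the self-hybridisation. Without RM11-1a replicate 1 there were 24 in RM11-1a.

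The segments higher in RM11-1a, in which more DNA bound than S288c DNA, lay mostly near chromosome ends. On chromosome 15, 14200 to 18279 had a median log2 ratio of 1.17 ± 0.12 (SD, n = 4) in RM11-1a and 0.83 ± 0.08 in the heterozygote, and 19315 to 21627 had 1.08 ± 0.15 and 0.61 ± 0.16. On chromosome 16, 23158 to 25656 had 1.04 ± 0.12 and 0.32 ± 0.16, and 934892 to 939655 had 0.97 ± 0.08 and 0.83 ± 0.26. On chromosome 4, 757794 to 758781 had 1.49 ± 0.43 and 0.60 ± 0.46. These 5 were also above 0 on the 25-mer and 30-mer RM11-1a arrays at 60 °C, between 0.85 and 1.21. On chromosome 12, 454465 to 490512 had 1.095 ± 0.73 but 0.08 and -0.18 on those arrays.

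The lowest of the segments lower in RM11-1a was on chromosome 4 from 1526814 to 1527408 (-3.36 ± 0.47 in RM11-1a, -1.17 ± 0.32 in the heterozygote), followed by chromosome 4 from 527716 to 530030 (-2.24 and -0.81), chromosome 14 from 3430 to 5626 (-1.92 and -0.95) and chromosome 1 from 207331 to 217066 (-1.76 and -0.43). Chromosome 8 from 212950 to 216153 had -1.37 and -0.28, chromosome 4 from 2802 to 10719 had -1.07 and -0.52, and chromosome 1 from 188461 to 189483 had -1.005 and -0.45. Chromosome 10 from 89018 to 89335 had -1.03 ± 0.72, but -0.005 and -0.06 on the 25-mer and 30-mer arrays. No test between the strains is given, since the segments were chosen on the RM11-1a arrays.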
